A study of Mus musculus with 19 samples.

How the data were processed

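Libraries (19) of poly(A)-selected heart RNA came from 2-month-old C57BL/6NTac mice raised germ-free and colonised with a normal or a dysbiotic gut microbiome. Groups were taken from the sample labels by sex and microbiome (4, 5, 5 and 5 mice). The labels give no cage, RNA batch or library batch, so each mouse was treated as independent in every test. Differences between the microbiomes cannot be told apart from differences of cage or batch where these follow the groups. Per the submitters' processing notes, the authors used cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and DESeq2. Those notes name the human build hg38, while the gene identifiers are mouse Ensembl IDs, 99.7% of which were found in GENCODE M21; the mouse build was not stated, so coordinates are those of GENCODE on GRCm38.

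The deposited table gives, per the file headers, FPKM per gene and library for 29726 genes. The authors also deposited a fold change (ratio), which was checked to equal the mean FPKM of the dysbiotic libraries over that of the normal libraries, and its log2 value. This ratio pools the sexes. The headers do not say whether the model behind the authors' p-value had a term for sex. The authors' q-value was checked to equal a Benjamini-Hochberg adjustment of that p-value. The table gives no read counts. From the smallest steps between low values, the depth was estimated at 16.4 to 23.0 M read pairs per library (median 19.2 M), but only 21.8% to 26.7% of low values fell on a step within a tolerance of 0.02, so counts were not recovered and no counting interval is given. Genes of the mitochondrial genome held 51.1% to 57.4% of summed FPKM.

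Genes with at least 1 FPKM in at least 4 samples (10866) were tested with limma-trend (limma 3.58.1, R 4.3.3, robust empirical Bayes) on log2(FPKM + 1), with 1 mean per group and all 19 libraries in 1 fit. With this pseudocount, log2 changes of genes near 1 FPKM are smaller than those of the FPKM themselves. The comparisons were dysbiotic against normal over both sexes, in males and in females, the difference between the sexes in that response, and female against male. Tests were two-sided, with a Benjamini-Hochberg adjusted p of 0.05 as the threshold. A count-based test had been planned if counts were given, and this test if only FPKM were. Of 35 gene lists, 34 had measured members and were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry; the neutrophil list had 0 measured genes. No list passed with an estimated correlation in the comparisons of microbiomes, and in the comparison of the sexes the X-linked (adjusted p = 0.00104) and Y-linked (adjusted p = 0.000598) lists passed with it.

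Bcl11b was below the filter, so log2 FPKM was compared by exact permutation within each sex (126 splits of the males, 252 of the females and 31752 of both). The groups, comparisons, tests, gene lists and most alternative settings were chosen before the data were examined, as was the rule for naming genes. That rule takes Bcl11b, then the 8 largest rises and 8 largest falls per microbiome comparison among genes that passed with a mean of at least 1 FPKM and a symbol that is not a predicted-gene name. It adds up to 4 members of each list by smallest p, and, for the sexes, the X and Y list genes and the 4 largest autosomal changes in each direction.

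Principal components used the 500 most variable genes. The model was tested on simulated data drawn independently per gene from a normal distribution with its own mean and spread, with changes added to 200 genes: at a log2 change of 0.5 it recovered 94% of the changed genes over both sexes, 89% in each sex, 70% in the interaction and 96% between the sexes, with 3 to 10 false calls. Alternatives covered scaling, filter, pseudocount, covariates, the replicate number as a block, the set test and leaving out each library in turn. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.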

Results

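Heart RNA was compared between formerly germ-free mice that received a normal or a dysbiotic gut microbiome, in 4 groups by sex. The groups held 4 males with the normal and 5 males with the dysbiotic microbiome, and 5 females with each. Values are FPKM per gene, log2 changes are of FPKM plus a pseudocount of 1 with their SE, and positive changes are higher with the dysbiotic microbiome. Adjusted p-values are two-sided, from limma with the Benjamini-Hochberg method over 10866 genes.

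Over both sexes (9 normal and 10 dysbiotic hearts), Ppargc1a, which encodes the coactivator PGC-1α that drives mitochondrial biogenesis, fell by 1.06 ± 0.13 on the log2 scale (adjusted p = 0.000127), from 25.4 ± 9.15 to 11.4 ± 1.87 FPKM (mean ± SD) in males and from 24.9 ± 5.27 to 11.1 ± 1.41 FPKM in females. Nr1d1, the clock repressor REV-ERBα, fell by 0.82 ± 0.07 (adjusted p = 4.02e-06), and Cdkn1a, the cell cycle inhibitor p21, fell by 0.73 ± 0.10. Rnf144b (-0.89 ± 0.13), Zbtb16 (-0.85 ± 0.18), Fam107a (-0.78 ± 0.14), the glycogen-targeting phosphatase subunit Ppp1r3c (-0.77 ± 0.13) and the glutathione-degrading enzyme Chac1 (-0.70 ± 0.08) also fell. The largest rises were in Pirt, a regulator of sensory TRP channels (0.78 ± 0.09, adjusted p = 8.07e-05), Lrrc3b (0.63 ± 0.07), Mid1ip1, a regulator of fatty acid synthesis (0.59 ± 0.08), the orphan receptor Gpr22 (0.58 ± 0.08), Lonrf1 (0.57 ± 0.05), Sbk3 (0.54 ± 0.14), Ccn5 (0.53 ± 0.09) and the clock output factor Dbp (0.53 ± 0.11). In all, 363 genes rose and 253 fell. Of these 616, 614 had the same sign in males and in females. That says little about agreement, because they were called on the mean of both sexes. With the pseudocount of 1, Ppargc1a was the 1 gene past an absolute log2 change of 1. The authors' log2 ratio of mean FPKM, without a pseudocount, was -1.161 for Ppargc1a. It also passed 1 in size for Pirt (1.199), Ccn5 (1.175) and Rnf144b (-1.075). The order of the changes depends on the pseudocount too, since that ratio was 0.569 for Mid1ip1, below Ccn5. The split depended on the scaling: 365 rose and 394 fell after median-ratio scaling, and 351 rose and 365 fell after upper-quartile scaling. Without a sex term 270 genes passed.

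**Figure D1:**
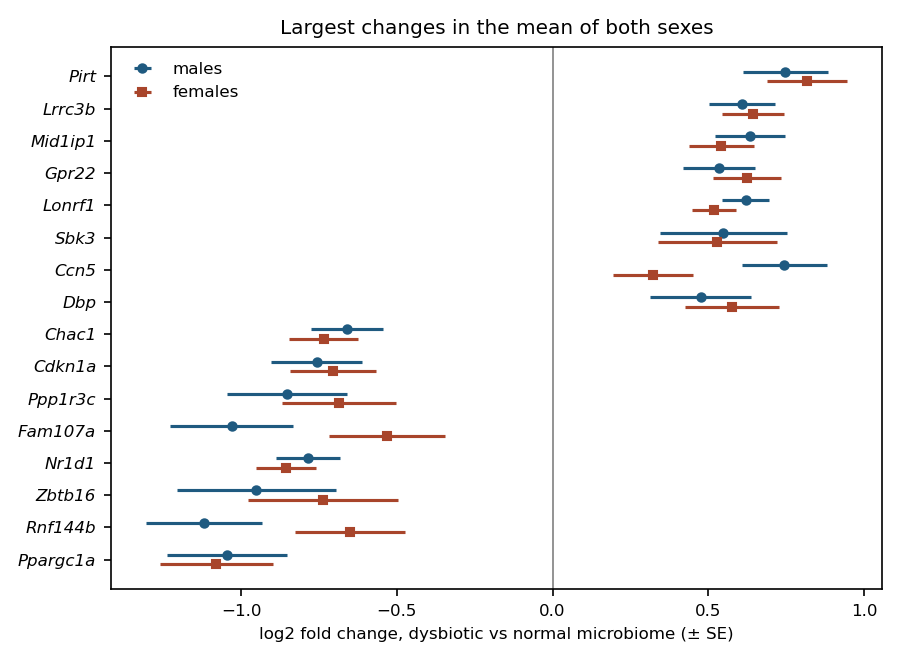
Log2 fold change with its SE (x axis) in males (circles, 4 normal and 5 dysbiotic hearts) and females (squares, 5 and 5) for the 16 genes with the largest changes over both sexes. The genes were picked on the mean of both sexes, which favours a shared sign. Each has the same sign in both sexes, from -1.06 for Ppargc1a to 0.78 for Pirt in their mean.

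Clock genes moved in both directions. Of 17 measured members of the circadian list, 9 rose and 3 fell (10 and 4 adjusted over the list alone), and the list as a set did not pass (adjusted p = 0.137, and 0.967 with an estimated correlation). Per3 (0.49 ± 0.06), Cry1 (0.30 ± 0.05) and Dbp rose, while Nr1d1 and Bhlhe40 (-0.44 ± 0.05) fell. Arntl, the core clock activator, was below the expression filter, at 0.874 ± 0.146 and 0.327 ± 0.0494 FPKM (mean ± SD) in normal and dysbiotic males and 0.562 ± 0.0629 and 0.257 ± 0.0595 FPKM in females; it was chosen after its values were seen. Of 16 glucocorticoid-responsive genes, 6 fell and none rose (7 and 0 adjusted over the list alone, adjusted p = 9.01e-07 for the list). Among them were Cdkn1a, Zbtb16, Klf15 (-0.52 ± 0.06) and Klf9 (-0.34 ± 0.04), both transcription factors induced by glucocorticoids; the adjusted p = 0.185 with an estimated correlation.

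Matrix genes were lower as a group over both sexes by camera at the preset correlation (adjusted p = 4.25e-09 for the list). The list had adjusted p = 0.639 with an estimated correlation and 0.146 by the rotation test fry. Its mean log2 change was -0.19 in females and -0.039 in males. Over both sexes, 7 of 37 measured collagens and matrix genes fell and 0 rose (12 and 0 adjusted over the list alone). They included Col5a3 (-0.33 ± 0.05), Col15a1 (-0.33 ± 0.07), Col3a1 (-0.31 ± 0.07) and Col1a1 (-0.24 ± 0.06), the last 2 the main fibrillar collagens of cardiac scar. Of 36 profibrotic signalling genes, 1 rose and 1 fell: Ccn5, a member of the CCN family known to oppose fibrosis, and Ccn2, its profibrotic relative, which fell by 0.59 ± 0.13 (adjusted p = 0.0137 for the gene, 0.632 for the list and 0.967 with an estimated correlation). Of 10 ventricular and conduction markers, 2 rose and none fell (6 and 0 adjusted over the list alone): the ventricular factor Irx4 (0.49 ± 0.06) and Gja5, the conduction connexin 40 (0.33 ± 0.08). That list passed with adjusted p = 0.00321, and had adjusted p = 0.185 with an estimated correlation. By camera the other 31 tested lists did not pass, but some had few measured members. Measured were 2 of 32 T and NK cell, 1 of 13 Schwann cell and neuron and 2 of 10 mast cell markers. With 4 of 28 cell cycle genes measured as well, the result of these lists says little. Of the 5 measured B and plasma cell markers, 1 rose and none fell. Their list had adjusted p = 0.0557 by camera, 0.0295 by fry and adjusted p = 0.639 with an estimated correlation. That list also passed camera after median-ratio scaling, upper-quartile scaling and the GC correction, without a sex term, with additive terms for sex and microbiome, and without normal male replicate 4, dysbiotic male replicates 1, 4 or 5, normal female replicate 3, or dysbiotic female replicates 1, 2 or 3. Without the expression filter 11 of 35 lists passed, 8 of them in addition: B and plasma cell, T and NK cell, Schwann cell and neuron, atrial, epicardial and mesothelial markers, and cell cycle, Y-linked and nuclear oxidative phosphorylation genes. The mitochondrial genome also passed without normal male replicate 1, dysbiotic male replicates 1 or 4, normal female replicate 2 or dysbiotic female replicate 5, nuclear oxidative phosphorylation without normal male replicate 4 or dysbiotic male replicate 4, and Y-linked genes without the latter. Without the 4 Alb-extreme libraries the mitochondrial genome and atrial markers passed.

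**Figure D2:**
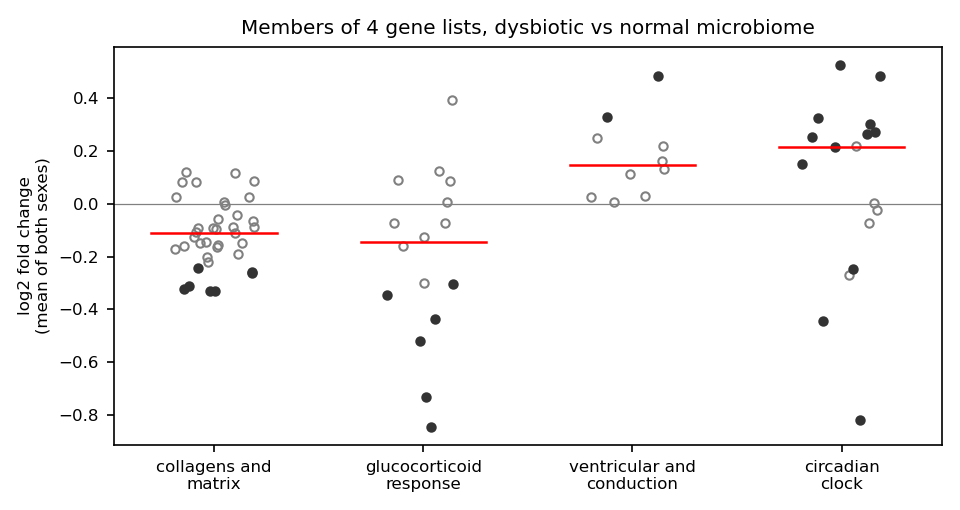
Log2 fold change over both sexes (y axis) of each measured member of 4 gene lists, with genes past the adjusted threshold filled and the list median as a red line. The 7 filled matrix genes and the 6 filled glucocorticoid genes lie below 0, and filled clock genes lie on both sides.

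Among the other lists, single members changed. The calcium channel subunit Cacnb2 rose by 0.44 ± 0.05, the gap junction gene Gja1 by 0.30 ± 0.08, and the potassium channel Kcnq1 fell by 0.15 ± 0.04, of 30 contractile and calcium-handling genes. Of 33 fatty acid oxidation genes, Ppargc1a and Pdk4 (-0.44 ± 0.11) fell and Slc27a1 rose (0.22 ± 0.05). Of 18 macrophage and monocyte markers, 2 fell: Lyve1 (-0.45 ± 0.08) and Cd14 (-0.24 ± 0.06). Of 21 inflammatory genes, 3 rose and 2 fell, among them the eosinophil chemokine Ccl11 (0.30 ± 0.07) and Ccl9 (-0.28 ± 0.05).

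Bcl11b, the zinc finger regulator named in the study's title and best known from T cell development, was higher with the dysbiotic microbiome in both sexes at a very low level. In males it went from 0.0586 ± 0.0175 (SD, n = 4) to 0.123 ± 0.0186 FPKM (n = 5), 2.14-fold by the means of log2 FPKM (exact permutation p = 0.00794, two-sided, the smallest the design can give). In females it went from 0.0496 ± 0.0182 (n = 5) to 0.129 ± 0.0287 FPKM (n = 5), 2.70-fold by the means of log2 FPKM (exact permutation p = 0.00794, also the smallest possible). Over both sexes the log2 difference of FPKM was 1.26 ± 0.18 SE, or 2.40-fold (exact permutation p = 3.15e-05, the smallest possible). These p-values take each mouse as independent, and cages are not given in the labels. The gene (ENSMUSG00000048251) lies on the minus strand of mouse chromosome 12 from 107910403 to 108003602 in build GRCm38. An estimated 5.56 to 26.8 read pairs per library lay behind these values, and the gene was below the expression filter. How the study came to choose Bcl11b is not recorded in the labels. If it was chosen on these samples, its difference is not independent evidence. Summed FPKM of 14 T cell genes differed by 0.24 ± 0.20 on the log2 scale (exact permutation p = 0.223), and of the 32 genes of the T and NK cell list by 0.28 ± 0.09 (exact permutation p = 0.00539). Without the receptor constant chains Trac, Trbc1 and Trbc2, which were left out after the values of all 14 genes were seen, the sum of the other 11 differed by 0.84 ± 0.24 (exact permutation p = 0.00211). Of 26 measured BCL11B partners and DNA methylation genes, 1 rose, the chromatin remodeller Smarca2 (0.21 ± 0.04), and none fell (adjusted p = 0.765 for the list and 0.967 with an estimated correlation). Tet1, an enzyme that oxidises methylated cytosine, was below the filter at 0.0480 ± 0.0118 and 0.0999 ± 0.0215 FPKM (mean ± SD) in normal and dysbiotic males and 0.0473 ± 0.0125 and 0.104 ± 0.0250 FPKM in females; it was chosen after its values were seen.

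**Figure D3:**
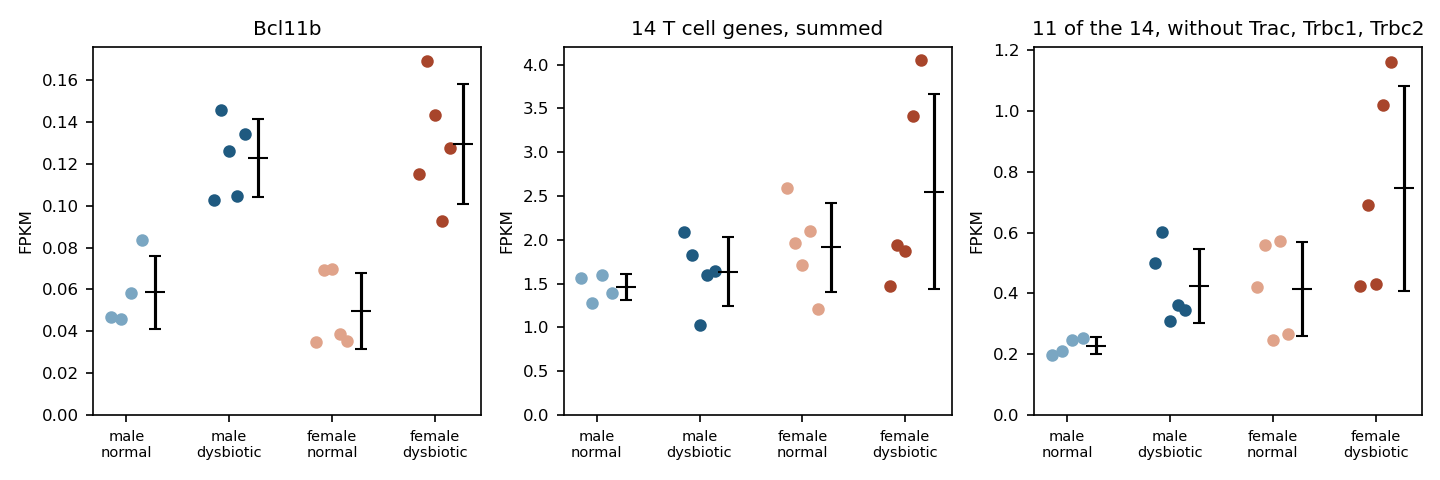
FPKM per heart (y axis, from 0) of Bcl11b, of the sum of 14 T cell genes and of the sum of 11 of them, in 4 groups, each point 1 heart and each bar the mean with its SD. Bcl11b does not overlap between microbiomes within a sex, with group means of 0.0586 and 0.123 FPKM in males and 0.0496 and 0.129 FPKM in females.

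In males (4 normal and 5 dysbiotic hearts), 104 genes rose and 103 fell. Scand1 fell by 1.80 ± 0.41 (adjusted p = 0.0358), the small heat shock protein gene Hspb1 by 1.38 ± 0.32, Rgcc by 1.22 ± 0.28, Rnf144b by 1.12 ± 0.19, the mitochondrial protein gene Chchd10 by 1.11 ± 0.26 and Ppargc1a by 1.05 ± 0.19. Pirt (0.75 ± 0.14), Ccn5 (0.74 ± 0.14), the cardiac transcription factor Mef2c (0.70 ± 0.13) and Lonrf1 (0.62 ± 0.07, adjusted p = 0.000968) rose. Of 16 glucocorticoid-responsive genes 3 fell (adjusted p = 2.98e-05 for the list, adjusted p = 0.51 with an estimated correlation), and of 3 Y-linked genes Eif2s3y fell by 0.36 ± 0.09 (adjusted p = 0.0361 for the list, adjusted p = 0.51 with an estimated correlation). The Y-linked list did not pass without normal male replicate 2 (adjusted p = 0.0884) or dysbiotic male replicates 3 (0.0608) or 5 (0.0550), nor after either scaling (0.0627 and 0.0520) or the GC correction (0.200). Of 23 cardiac stress genes 1 rose and 1 fell, and the list was higher by a mean log2 change of 0.20 (adjusted p = 0.0494, adjusted p = 0.961 with an estimated correlation). Dysbiotic male replicate 3 carried most of this, with a list score of 0.74 against -0.051 to 0.34 in the other dysbiotic males, and the change was 0.079 without it (adjusted p = 0.478). The change was 0.13 without normal male replicate 4 (adjusted p = 0.167), and the list did not pass without normal male replicate 1 (0.349), dysbiotic male replicate 5 (0.0550), normal female replicate 3 (0.0531) or dysbiotic female replicates 1, 2 or 5 (0.0523, 0.0542 and 0.0618), nor after upper-quartile scaling (0.0520). The 13 genes of the mitochondrial genome were lower by a mean of 0.073, none past the threshold (adjusted p = 0.0494, adjusted p = 0.961 with an estimated correlation). Without dysbiotic male replicate 5, the heart lowest in Alb of its group, the mean was -0.029 (adjusted p = 0.576). That list also did not pass without normal male replicates 2 or 4 (0.0968 and 0.379), dysbiotic male replicates 2 or 3 (0.156 and 0.0681), normal female replicate 3 (0.0531) or dysbiotic female replicates 1 or 2 (0.0523 and 0.0542), nor after either scaling (0.149 and 0.146), the GC correction (0.721) or without the filter (0.0788). With a pseudocount of 0.1 the Y-linked, cardiac stress and mitochondrial genome lists had adjusted p = 0.189, 0.0657 and 0.0657. Of 37 matrix genes 1 fell, and that list did not pass (adjusted p = 0.0509, and 0.961 with an estimated correlation). The male count was 97 without the expression filter, 69 when only males were fitted, 106 with replicate number as a block, 60 without normal male replicate 2, and 1 with a covariate built from the genes of the interaction, which was added after the data were seen. The split was 124 and 173 after median-ratio scaling, 135 and 145 after upper-quartile scaling, 108 and 181 after the GC correction, 22 and 47 when only males were fitted, 172 and 86 without normal male replicate 1, and 44 and 84 without replicate 4.

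In females (5 hearts per microbiome), 202 genes rose and 107 fell. Scand1 rose by 2.47 ± 0.39 (adjusted p = 0.00285), the neurotrophic factor gene Nrtn by 2.02 ± 0.29, Zfp771 by 1.80 ± 0.26, Hspb1 by 1.42 ± 0.30, Chchd10 by 1.37 ± 0.24 and the transcriptional coactivator Cited4 by 1.21 ± 0.16. Ppargc1a fell by 1.08 ± 0.18, Nr1d1 by 0.86 ± 0.10, the mitochondrial nucleotide carrier Slc25a33 by 0.81 ± 0.10 and Chac1 by 0.74 ± 0.11. Of 37 matrix genes 7 fell and none rose (19 and 0 adjusted over the list alone, adjusted p = 2.71e-13 for the list, adjusted p = 0.324 with an estimated correlation and 0.107 by fry), including Col15a1 (-0.49 ± 0.09), Col3a1 (-0.46 ± 0.09) and Col1a1 (-0.40 ± 0.09). Of 16 glucocorticoid-responsive genes 3 fell (adjusted p = 0.000168 for the list, adjusted p = 0.324 with an estimated correlation and 0.130 by fry). Ventricular markers were higher, with 2 of 10 past the threshold (adjusted p = 0.00941 for the list, 0.0172 by fry, adjusted p = 0.324 with an estimated correlation), as were B and plasma cell markers, with 1 of 5 (adjusted p = 0.0110, 0.0352 by fry, adjusted p = 0.324 with an estimated correlation). Dysbiotic female replicates 5 and 4 had B and plasma cell scores of 1.39 and 0.79 against -0.22 to 0.090 in the other dysbiotic females, and the highest sums of 14 T cell genes (4.05 and 3.42 FPKM). The mean log2 change of that list was 0.65, and 0.40 without replicate 5 (adjusted p = 0.0559), and with at least 1 FPKM asked in 10 samples its adjusted p was 0.0774. The split was 215 and 177 after median-ratio scaling and 190 and 168 after upper-quartile scaling, and the count was 167 without normal female replicate 1 and 585 with array weights. The same covariate left 1 gene.

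The response differed between the sexes for 43 genes, 41 of them with a more positive change in females. All 43 had opposite signs in the sexes. The difference, female minus male, was 4.27 ± 0.56 for Scand1 (adjusted p = 0.00248), 3.11 ± 0.43 for Nrtn, 2.89 ± 0.39 for Zfp771, 2.80 ± 0.43 for Hspb1, 2.48 ± 0.35 for Chchd10, 1.59 ± 0.27 for the small nucleolar ribonucleoprotein gene Imp3 and 1.57 ± 0.23 for Cited4. Hspb1 was at 126 ± 30.8 and 50.3 ± 22.8 FPKM (mean ± SD) in normal and dysbiotic males, and at 43.4 ± 8.24 and 122 ± 37.0 FPKM in females. Hsp25-ps1 (2.65 ± 0.39), a pseudogene of Hspb1 that can take its reads, is uncertain. In the other direction were Coq10b (-0.34 ± 0.07) and Arid5a, which was below the mean level set for naming and was chosen after its values were seen. The matrix list had a more negative change in females (adjusted p = 9.82e-05, adjusted p = 0.896 with an estimated correlation), with no single member past the threshold. The count was 22 without the expression filter, and ran from 24 without normal male replicate 2 to 102 without dysbiotic male replicate 5.

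**Figure D4:**
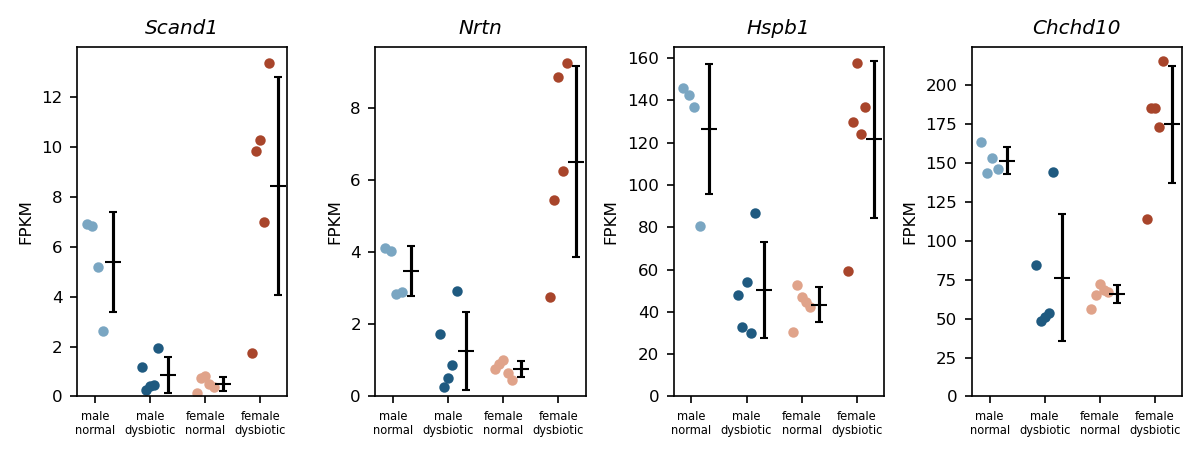
FPKM per heart (y axes, from 0) of 4 genes whose response differed between the sexes, each point 1 heart and each bar the mean with its SD. Hspb1 means were 126 and 50.3 FPKM in normal and dysbiotic males and 43.4 and 122 FPKM in females.

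Between females and males (10 and 9 hearts), 2548 genes were higher and 863 lower in females. The Y-linked genes Ddx3y (-3.09 ± 0.04) and Eif2s3y (-3.01 ± 0.06) were lower, and Xist, the X inactivation transcript (1.84 ± 0.05), and the X inactivation escapee Kdm6a (0.63 ± 0.03) were higher. Autosomal genes higher in females included the adipocyte protease Cfd (1.94 ± 0.33), the heme-degrading enzyme Hmox1 (1.88 ± 0.16), Klhl33 (1.01 ± 0.09) and Art5 (0.98 ± 0.07). Lower in females were the complement gene C7 (-1.34 ± 0.07), skeletal actin Acta1 (-1.12 ± 0.32), Nmrk2 (-1.02 ± 0.27) and the stress-responsive Ankrd1 (-0.92 ± 0.18, adjusted p = 0.000954). Of 23 cardiac stress genes, 3 were higher and 11 lower (adjusted p = 6.22e-05 for the list, adjusted p = 0.7 with an estimated correlation). Of 37 matrix genes 4 were higher and 8 lower (adjusted p = 0.000203 for the list, 0.169 by fry), and of 16 glucocorticoid-responsive genes 8 were higher and none lower (adjusted p = 0.00709, 0.000128 by fry), each with adjusted p = 0.7 with an estimated correlation. Of 13 genes of the mitochondrial genome 3 were lower (adjusted p = 0.00709, adjusted p = 0.7 with an estimated correlation), but the list did not pass after the GC correction (0.385). Epicardial and mesothelial markers (0 higher and 1 lower of 5) and red blood cell genes (0 and 0 of 7) were lower as lists (adjusted p = 0.0174 for each, adjusted p = 0.496 and 0.7 with an estimated correlation). Neither passed after median-ratio scaling (0.0795 and 0.0591), upper-quartile scaling (0.0680 and 0.0588) or the GC correction (0.0533 for each), nor did the epicardial list with 1 FPKM asked in 10 samples (0.226). Of 25 unfolded protein and oxidative stress genes 10 were higher and 2 lower (adjusted p = 0.0413 for the list, adjusted p = 0.7 with an estimated correlation). That list did not pass without normal male replicate 3 (0.0591), dysbiotic male replicates 4 or 5 (0.0526 and 0.0706) or normal female replicate 3 (0.0520), nor with 1 FPKM asked in 10 samples (0.0597). Of 36 profibrotic signalling genes 5 were higher and 5 lower (adjusted p = 0.0439 for the list, adjusted p = 0.747 with an estimated correlation). It did not pass without normal male replicates 1 or 3 (0.0552 and 0.0589), dysbiotic male replicate 4 (0.0576), normal female replicates 3 or 5 (0.0543 and 0.0585) or dysbiotic female replicate 1 (0.0681), nor after either scaling (0.0831 and 0.0790), the GC correction (0.0614) or either other filter (0.0693 and 0.0849). The split was 1769 and 1758 after median-ratio scaling and 1724 and 1663 after upper-quartile scaling.

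The authors' deposited table, whose fold change pools the sexes, gave Bcl11b a fold change of 2.35 (q = 1.95e-07). It held 534 genes at q under 0.05, of which 271 were higher and 263 lower; 439 of them were tested here and 374 passed here, all in the same direction. The authors' own mark of significance was on 36 genes, 29 higher and 7 lower. Across the 10866 genes, which are not independent replicates, male and female log2 changes had a Pearson r of 0.0792 and a Spearman rho of 0.237; in 78 of 100 splits of the samples within each sex, the real one included, r was as far from 0. Of genes called in each sex, 81 were called in both, and 72 of these changed in the same direction, where independence gives 2.95. In a principal component analysis, component 1 held 50.5% of the variance and was led by liver transcripts such as Alb and Apoa2. Alb ranged from 0.0522 to 449 FPKM between hearts, unevenly between the microbiomes. The lowest values were in dysbiotic male replicate 5 (0.574) and dysbiotic female replicates 3 (0.587) and 5 (0.0522). The lowest normal heart had 31.5 FPKM. Of the 15 lung, liver and thymus transcripts listed, 5 passed the expression filter, the liver genes Alb, Apoa1, Apoa2, Ttr and Serpina1c. Their mean log2 change was -0.95 over both sexes, and the list did not pass (adjusted p = 0.137 by camera). No lung or thymus gene of the list was tested, so this result says nothing about RNA from those tissues. Component 2 (10.2%) separated the sexes, component 3 (7.22%) carried Scand1, Nrtn and Hspb1, and 58.0% of component 4 (5.60% of the variance) lay between the microbiomes.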

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

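The tests of a shared library factor, GC content and length in this part were chosen after the interaction was seen, and the criteria for GC content and length were set before the values of those tests were known. Responses to the dysbiotic microbiome differed between the sexes, female minus male on the log2 scale, for Scand1 (4.27), Nrtn (3.11), Zfp771 (2.89), Hspb1 (2.80), Hsp25-ps1 (2.65), Chchd10 (2.48), Imp3 (1.59), Cited4 (1.57) and Coq10b (-0.34), each by the interaction test of limma. On the same contrast camera called 4 gene lists, all more negative in females: collagens and matrix (adjusted p = 9.82e-05), cardiac stress (adjusted p = 0.0176), profibrotic signalling (adjusted p = 0.0228) and red blood cell genes (adjusted p = 0.0228). With an estimated correlation their unadjusted p-values were 0.191, 0.283, 0.222 and 0.185, and the adjusted p was 0.896 for each. The cardiac stress list did not pass without normal male replicates 1 or 4 (adjusted p = 0.0989 and 0.0652), dysbiotic male replicate 3 (0.103) or normal female replicate 3 (0.0555), and its mean difference went from -0.23 to -0.11 without dysbiotic male replicate 3. The profibrotic list did not pass without normal male replicate 4 (0.0652), dysbiotic male replicates 3 or 4 (0.0662 and 0.0501), normal female replicates 1 or 4 (0.0636 and 0.0518) or dysbiotic female replicates 1 or 3 (0.109 and 0.0516). Red blood cell genes did not pass without normal male replicate 1 (0.194), dysbiotic male replicates 2 or 3 (0.0864 and 0.0713), normal female replicates 1 or 3 (0.0662 and 0.0752) or dysbiotic female replicates 1 or 3 (0.0726 and 0.0780).

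The 43 genes of the interaction were weighed as 1 pattern. Bias by GC content or transcript length does not account for it alone: although their median GC content was 56.1% against 50.1% for all tested genes, 42 of the 43 genes still passed after a correction on GC content and 42 after a correction on length, with a median log2 difference of 0.94 before and 0.94 and 0.97 after. A factor shared by these genes across libraries may contribute, since within groups each gene's correlation with the sum of the others had a median of 0.740, above the 95th percentile of 0.455 in 1000 sets of genes of like expression. What the factor stands for, such as handling of the tissue or of the libraries, is not recorded in the labels, and a response that differs by sex stays open and untested. Of 100 splits of the samples, the real one included, 2 called at least as many genes, with 43 in the real split and 74 in the highest other. Few splits reached the real count, but another exceeded it, so chance is made less likely and is not excluded. Why 1 other split called more genes was not tested.

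In 368 group tests for a sample far from the others of its group, 22 stood out, where chance gives about 1 in 20, or 18.4. Dysbiotic male replicate 5 had 0.574 FPKM of the liver transcript Alb against 180 to 209 in its group, a component 1 score of 17.1, and 0.400 FPKM of Xist. Normal female replicate 1 had an estimated depth of 22.1 M read pairs and 4.45 FPKM of Cd14. Dysbiotic female replicate 2 had a matrix list score of -0.00407 against -0.186 to -0.141 in the others. Dysbiotic male replicate 3 had 15.4 FPKM of Cdkn1a, 992 of Acta1 and 640 of Ankrd1. Normal male replicate 2 had 489 FPKM of Pdk4 and 668 of Acta1, and normal male replicate 4 had 12.8 of Bhlhe40, 6.59 of Col6a2, 80.5 of Hspb1 and 9.19 of Endog. Normal male replicate 1 had 1.44 FPKM of Ccn5. Normal female replicate 5 had 31.9 FPKM of Nr1d1, 498 of Pdk4 and 47.4 of Cfd. Dysbiotic female replicates 1, 3 and 4 had 54.7 FPKM of Mid1ip1, 0.0224 of Eif2s3y and 13.6 of Lyve1, in that order.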

How the results depend on the processing

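Array weights, GC and length corrections, liver and library-factor covariates, leaving out 4 Alb-extreme libraries, and other filters, scalings and models for gene lists were added after the data were seen. The planned count-based tools (DESeq2, voom with quality weights, TMM) could not be run without counts. Of 6309 values of named genes under all alternatives, 5904 kept their direction and side of the threshold, 313 no longer passed, 87 newly passed and 5 reversed. All 5 reversed with the library factor, the mean of the 43 interaction genes, as a covariate: Hsp25-ps1 in males (0.0078), and in females Hsp25-ps1 (-0.14), Hspb1 (-0.38), Chchd10 (-0.039) and Endog (-0.24). That covariate left 1 gene in males and 1 in females and moved the male-female r to -0.683, while 506 genes passed over both sexes; its genes were picked for a difference between the single-sex responses, which it takes up by construction.

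Over both sexes 270 genes passed without a sex term. Males gave 97 without the filter, 69 with only males fitted, 106 with replicate number as a block and 362 with the length correction. Females gave 585 with array weights. The interaction gave 22 without the filter, 85 with array weights, 72 with the GC and 71 with the length correction. With an absolute log2 change of at least 1 the counts were 1 over both sexes, 10 in males, 14 in females, 18 in the interaction and 11 between the sexes. Where none is named, the cause was not tested. Without the 4 Alb-extreme libraries 460 genes rose and 194 fell over both sexes. With an estimated correlation the adjusted p was 0.639 for matrix genes, 0.185 for glucocorticoid genes and 0.185 for ventricular markers, and fry gave 0.146 for matrix genes. Component 1 held 39.5% of the variance with 2000 genes.

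The replicate block gave 514 genes over both sexes, 257 in females, 36 in the interaction and 3110 between the sexes, and a Bcl11b difference of 1.29 (exact permutation p = 0.0034). Numbers did not pair mice (median residual r of 27 same-number pairs -0.0318). Bcl11b kept its direction and call under every alternative run, with a log2 difference of 0.55 at a pseudocount of 0.1 and 0.0952 at a pseudocount of 1.

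Leaving out each library gave 444 to 676 genes over both sexes, 60 to 258 in males, 167 to 357 in females, 24 to 102 in the interaction and 2830 to 3819 between the sexes. Male counts were 60, 81 and 128 without normal male replicates 2, 3 and 4, and 105 and 134 without dysbiotic male replicates 2 and 3. Female counts were 167, 201 and 172 without normal female replicates 1, 3 and 4. Interaction counts were 24 and 25 without normal male replicates 2 and 3, 27, 28 and 102 without dysbiotic male replicates 3, 4 and 5, 26, 27, 28 and 28 without normal female replicates 1, 3, 4 and 5, and 28 and 27 without dysbiotic female replicates 2 and 5. Adjusted p ran from 1.65e-12 to 3.33e-07 for matrix genes, 9.24e-09 to 2.59e-05 for glucocorticoid genes and 0.000995 to 0.0121 for ventricular markers, Bcl11b from 1.21 to 1.36, and r from -0.0964 to 0.169.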

Other observations

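Apart from the tests of genes and gene lists and the splits of the samples, all tests in this part were chosen after the patterns were seen. The criteria for GC content, liver RNA and genes of like level were set before the values of those tests were known. Those for clock phase, the T cell sums and the library factor were changed after their first values were seen. Immune and vessel genes outside the lists named so far changed singly. Of 20 endothelial markers, Emcn rose by 0.29 ± 0.05 and Tek by 0.17 ± 0.05, and of 17 fibroblast markers, Cd248 rose by 0.41 ± 0.08 while Col1a1 and Col3a1 fell. Of 30 interferon-response genes, Gbp6 fell by 0.28 ± 0.06 and Ifit3b rose by 0.18 ± 0.05. Of 27 glucose and ketone genes, Txnip fell by 0.34 ± 0.09. None of these lists passed, with adjusted p-values of 0.78, 0.785, 0.91 and 0.91 in that order.

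Clock genes differed between the microbiomes over both sexes. Liver RNA and a GC bias along the average trend over all genes do not account for this alone. After the GC correction 11 of the 12 called clock genes still passed, and 11 with the liver transcripts as a covariate. A shifted clock phase may contribute but was not decided. The median log2 change of the Per and Dbp phase was 0.28 above that of the Arntl phase (SE of the difference 0.05). Yet the Arntl-phase median was -0.02 with members going both ways, from -0.40 for Arntl to 0.30 for Cry1. That median was the value of Npas2, at a mean of 0.269 FPKM. At that level the pseudocount shrinks log2 changes, as it does for Arntl (0.486 FPKM). Members of the Per and Dbp phase also went both ways, from -0.27 for Ciart to 0.53 for Dbp. Nr1d1, which fell, was in neither phase. By the first criterion, which did not ask each median to differ from 0, the shift would have been taken as present. All 12 called genes had the same direction in both sexes, which decides nothing because they were called on the mean of both sexes (8 of the list passed in males and 6 in females). An effect of the microbiome and a different time of day at collection cannot be told apart, since the labels give no collection times.

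Higher Bcl11b was weighed against 3 explanations. A general rise of genes at this low level was argued against by a median log2 difference of 0.084 in 1635 genes of like level. Bcl11b ranked 17 from the top by this difference, so some genes of like level rose more. The median does not test whether Bcl11b was chosen for its rise. The factor behind the interaction genes was argued against by its direction, down by 0.60 in males and up by 0.82 in females. A factor that goes opposite ways cannot by itself raise Bcl11b in both sexes. With it as a covariate the Bcl11b differences were 1.14 ± 0.40 in males and 1.37 ± 0.48 in females. A rise in at least 1 sex had to stay, so these differences add little. More T cells in the dysbiotic hearts may contribute and were not decided, because 3 sums disagree. The sum of 14 T cell genes, named first, differed by 0.24 and that of the whole T and NK cell list by 0.28, both with 95% intervals below that of Bcl11b, while the sum of 11 genes, chosen after Trac was seen to hold a median of 56.1% of the first sum, differed by 0.84 with an interval that reaches the Bcl11b value. Most of these genes were far below 1 FPKM, and a change within heart cells was not tested.

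Splits of the samples, 100 per comparison with the real one included, were also counted. Over both sexes 1 of 100 gave as many genes (616, highest other 1), as did 1 of 100 in males (207, highest other 49). The same held for 1 of 100 in females (309, highest other 2) and 1 of 100 between the sexes (3411, highest other 2). Since 100 splits can show no share below 1 of 100, chance is made less likely for these counts and is not excluded. Splits do not test differences of cage or batch that follow the groups.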
